A study of Homo sapiens with 3 samples.

How the data were processed

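Small RNA of exosomes from MCF7 cells was measured in 3 libraries, 1 each for Control, KD and RE. Per the labels' protocols, RNA was extracted from the exosomes with a miRNeasy kit, and libraries were made with the VAHTS small RNA kit and sequenced on an Illumina instrument. The deposited values are counts, whole numbers of reads per mature miRNA, which the authors gave for 972 known and 147 predicted names. Per the submitters' processing notes, Bowtie, edgeR and build GRCh38 were used, with no role or version stated. The counting tool, the miRNA database release, the treatment of reads that match several places and the predictor of the new miRNAs are not given in the sources used here. Reads shared by near-identical miRNAs, such as let-7 members, may therefore be split or counted more than once, and 5 pairs of predicted names with at least 30 reads had identical counts in every library. Small RNA kits in general ligate adapters with a preference for some sequences and amplify by PCR, and no molecular identifiers are described, so intervals cover counting error only.

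Totals ranged from 588597 to 2720939 counts. A floor of 3 counts corresponds to 1.44 CPM in Control, 5.10 CPM in KD and 1.10 CPM in RE. Counts were divided by the library total (CPM) and compared as log2(CPM + 1), so folds of low miRNAs are understated. A miRNA was tested, in the sense of entering the counts, with a mean of at least 10 CPM and at least 30 reads over the 3 libraries, which kept 259 known and 69 predicted names. The limit was a 2-fold difference. With 1 library per group no statistical test was made, and exact Clopper-Pearson 95% intervals were computed for shares of counts and for the ratio of each pair of counts. Alternative scalings used TMM factors from edgeR 4.0.16, median-of-ratios size factors from DESeq2 1.42.0 (the size-factor scale), and the total without the 5 most abundant names. Of these 5 names the last was a tie of novel_miR_117 and novel_miR_51, which have identical counts, and only 1 of the pair was left out. A total of known miRNAs was added after the data were examined. No count model of either package was fitted.

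The miRNAs named were set by a rule made before the data were examined. It took, for each pair, the 10 highest and 10 lowest log2 folds at a mean of at least 50 CPM, the 10 most abundant miRNAs, and the 4 most abundant members of each fixed list. List members at least 2-fold different in KD at that abundance were also taken, which with miR-1290 gave 139 names. miR-1290 was taken whatever its level because the study is known for it, so its choice was not independent of the study. The 23 lists were fixed at the same time and covered miRNA families, reported promoters and suppressors of breast cancer invasion, and markers of other cell types. A list with at least 3 tested members was described by its median and that median's percentile among 10000 random lists of the same size, each member drawn from the 30 known miRNAs nearest in mean CPM. Percentiles are those of the CPM median unless stated, describe these libraries and are not tests. Return in RE was set beside 100 simulated sets of unchanged libraries.

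Hairpin positions, host genes and sequences came from GENCODE release 29 on GRCh38, where 950 of the 972 known names (257 of 259 tested) matched by gene name, so coordinates are those of hairpin genes and not of mature miRNAs. GC was computed over the 5′ or 3′ side of the hairpin as a stand-in for the mature sequence. For names that give no side, such as miR-1246 and miR-1290, the whole hairpin was used. Where a name matched several hairpins their mean was taken, so let-7f-1-3p and let-7f-2-3p have the same GC value. On simulated counts with 200 of 1119 names changed 4-fold in 20 draws, 97.9% of changed tested names were recovered by CPM and 98.9% by size factors for KD over Control, with 5.43% and 1.74% of unchanged names called. For RE over Control 98.6% and 99.8% were recovered, with 1.06% and 0.0759% of unchanged names called. These simulations hold counting error only. Other alternatives were pseudocounts of 0.1 and 10 CPM, no filter and a filter at 100 CPM, limits of 1.5-fold and 4-fold, and leaving out names listed as fragments of other RNA classes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.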

Results

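Small RNA was sequenced from exosomes, the small vesicles that cells release, collected from the culture medium of MCF7 cells. MCF7 is an established human breast cancer line of the luminal, oestrogen receptor-positive type. The cells had been transfected for 24 h with a non-targeting siRNA (Control), with an siRNA against LSD1 (KD) or with a plasmid that expresses LSD1 (RE), and were then kept in serum-free medium for 36 h. LSD1, the product of the KDM1A gene, is a histone demethylase. The series presents RE as a rescue of the knockdown, but the labels do not say whether RE cells also received the siRNA. Each group had 1 library, so no difference has a replicate check, and none below was tested. LSD1 mRNA was not measured in these small RNA libraries, so the labels were not checked against it. The libraries held 2077618 counts in Control, 588597 in KD and 2720939 in RE, spread over 972 known and 147 predicted miRNA names. Intervals are 95% intervals that cover counting error only.

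The composition of the 3 libraries differed widely. Predicted miRNAs, whose sequences are not identified here, took 42.5% of the Control counts (exact binomial interval 42.4 to 42.6%), 10.98% of KD (10.9 to 11.1%) and 40.0% of RE (39.98 to 40.1%). The similar shares of Control and RE were divided differently among the same abundant names. In the same order, novel_miR_139 had 219010, 11706 and 77094 CPM, and novel_miR_117 and novel_miR_51 each had 67115, 14064 and 159745. The last 2 have identical counts in each library, so the same reads may be counted under both names, in these shares and in the totals. miR-1246 took 15.3% of Control, 6.66% of KD and 29.5% of RE. miR-21-5p, a miRNA that is abundant in many tumours, took 17.4%, 11.7% and 5.06% in the same order, while miR-100-5p took 2.54%, 17.4% and 4.75%. Known miRNAs outside these, miR-1290 and the let-7 family made up 8.37% of Control, 34.7% of KD and 14.2% of RE. When every library was thinned to the 588597 counts of KD, 422 known miRNAs were detected in Control, 659 in KD and 553 in RE. The choice of scaling moved the median of all 328 tested miRNAs. The median log2 fold of KD over Control was 1.74 by library total (CPM), 0.98 without the 5 most abundant names in the total, 0.27 with TMM factors and -0.14 with median-of-ratios size factors. For RE over Control the medians were 0.13, 0.10, 0.10 and -0.09, and for RE over KD they were -1.51, -0.79, -0.08 and 0.13. Log2 folds below are therefore given by CPM and then on the size-factor scale, and directions are drawn where these 4 scalings share them.

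**Figure D1:**
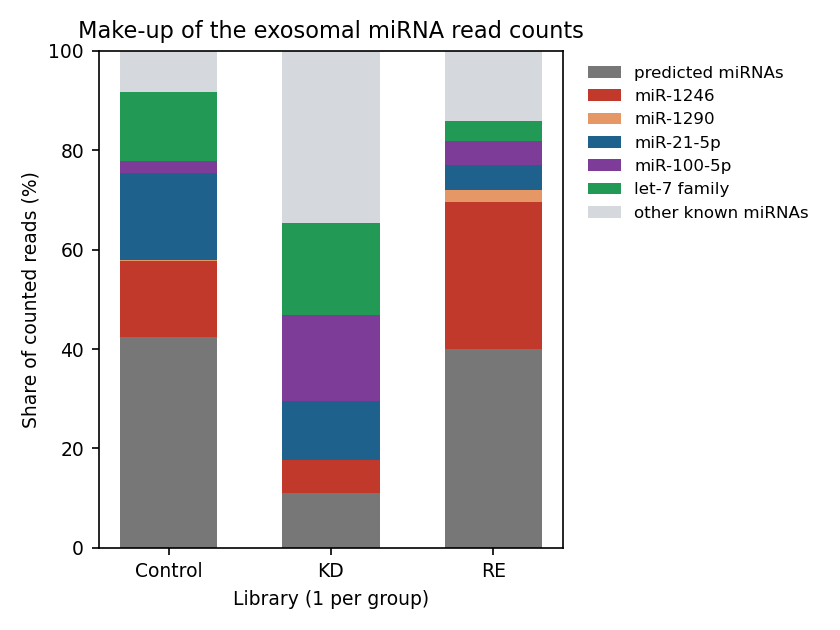
Share of all counts (percent, vertical axis) taken by each class of miRNA in the Control, KD and RE libraries. Predicted miRNAs took 42.5% of Control and 40.0% of RE but 10.98% of KD, and known miRNAs outside the classes shown by name took 34.7% of KD. The predicted share counts novel_miR_117 and novel_miR_51, which have identical counts, as separate names.

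The comparison of KD with Control asks which exosomal miRNAs differ after LSD1 knockdown, in a study concerned with invasion and migration. miR-375-3p, which is abundant in luminal breast cells, stood at 46.7 CPM in Control and 1335 CPM in KD. Its log2 fold was 4.81 by CPM (counting interval 4.53 to 5.16) and 2.90 on the size-factor scale. miR-423-5p was higher in KD by 4.69 (4.55 to 4.86) and 2.77, and miR-128-3p, a brain-enriched miRNA, by 4.70 (4.47 to 4.99) and 2.79. The liver miRNA miR-122-5p had the highest fold of these, 5.12 (4.49 to 6.33) and 3.29, from 12 reads in Control and 138 in KD. Lower in KD under each of the 4 scalings were miR-1246, with log2 folds of -1.20 (-1.21 to -1.18) and -3.12, let-7f-5p at -1.21 (-1.27 to -1.15) and -3.13, miR-96-5p at -1.82 (-2.28 to -1.42) and -3.72, and miR-29b-3p at -1.61 (-2.18 to -1.12) and -3.50.

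By CPM, 215 of the 328 tested miRNAs were at least 2-fold higher in KD and 29 at least 2-fold lower. That split was 161 to 57 without the 5 most abundant names, 94 to 77 with TMM factors and 67 to 102 with size factors. Under each of the 4 scalings, 67 were higher (59 known) and 29 lower (11 known). Others in the higher group were miR-760 (4.59 and 2.71), miR-615-3p (4.35 and 2.51), miR-1303 (4.22 and 2.35), miR-196a-5p (3.80 and 1.91) and miR-26a-5p (3.74 and 1.82). The sequence of miR-375 lies at chromosome 2, 219001645 to 219001708 on the minus strand, in no annotated host gene on that strand. The miR-423 hairpin lies at chromosome 17, 30117079 to 30117172, in an exon of NSRP1, and that of miR-122 at chromosome 18, 58451074 to 58451158, in an exon of MIR122HG. The miR-615 hairpin, at chromosome 12, 54033950 to 54034045, is in an intron of HOXC4 and HOXC5. miR-128-3p, let-7f-5p and miR-29b-3p each come from 2 hairpin genes whose reads cannot be separated. The predicted miRNA with the most counts in Control, novel_miR_139, held 219010 CPM there and 11706 CPM in KD, log2 folds of -4.23 and -6.15. In the opposite direction, novel_miR_128 went from 2366 CPM in Control to 33772 CPM in KD, 3.83 and 1.91.

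Members of the same family differed in KD. In the let-7 family, whose 5p products repress RAS and HMGA2, 8 of 14 tested miRNAs were at least 2-fold higher by CPM and 1 lower. On the size-factor scale none was higher and 6 were lower. The 14 include products of the other, 3p side of let-7 hairpins: let-7a-3p, let-7d-3p, let-7f-1-3p, let-7f-2-3p and let-7i-3p. Among the 5p products, let-7b-5p, let-7c-5p (1.66 by CPM) and let-7d-5p (1.57) were higher by CPM. The 3p products higher by CPM included let-7d-3p (2.48) and let-7f-1-3p (2.17). let-7b-5p had log2 folds of 2.89 (2.81 to 2.98) and 0.97. let-7a-5p had 0.03 and -1.89, let-7g-5p 0.41 and -1.51, and let-7i-5p 0.48 and -1.45, so their direction depended on the scaling. Within a library no scaling enters: there were 12.5 reads of let-7f-5p per read of let-7b-5p in Control (11.9 to 13.1) and 0.728 in KD (0.693 to 0.765). In the miR-183 cluster, reads of miR-96-5p per read of miR-183-5p were 0.553 in Control (0.501 to 0.610) and 0.0229 in KD (0.0169 to 0.0303). The cluster lies on chromosome 7 and holds miR-96 at 129774692 to 129774769 and miR-183 at 129774905 to 129775014, both on the minus strand. Reads of miR-29b-3p per read of miR-29a-3p, which share a seed and repress collagen mRNAs, were 0.0663 in Control (0.0595 to 0.0737) and 0.00729 in KD (0.00504 to 0.0102). On the X chromosome, miR-424-5p had folds of -1.40 and -3.27, while miR-424-3p from the same hairpin had 2.89 and 0.98, and miR-503-5p, encoded beside it, 3.22 and 1.30. Across the 257 tested known miRNAs with a matched hairpin, the fold was higher for miRNAs from GC-rich hairpin arms, or whole hairpins where the name gives no arm. The Spearman rho was 0.43 across miRNAs, which are not independent replicates. In 4 equal bins by GC, the size-factor median was -0.54 in the lowest and 0.94 in the highest.

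The miR-200 family, which represses ZEB1 and ZEB2 and is typical of epithelial cells, had 6 of 6 members at least 2-fold higher in KD by CPM and 2 of 6 on the size-factor scale, miR-200b-3p (3.62 and 1.71) and miR-200c-3p (3.27 and 1.35). Its median of 2.35 by CPM was at percentile 75.2 of random lists matched on expression. Of 17 fixed lists with at least 3 tested members, 14 lay between percentiles 2.5 and 97.5. All 5 tested members of the imprinted cluster on chromosome 14 were higher in KD under both scalings, with medians of 3.84 and 2.22 (percentile 99.7). They had few reads, such as 5 in Control and 33 in KD for miR-381-3p, with a fold of 4.07 (3.18 to 6.26), and passed the abundance filter through KD and RE, which favours members that are higher there. A sum over all 43 detected members, added after the data were examined, needs no such filter and gave 40 reads in Control and 174 in KD, with folds of 3.94 (3.44 to 4.47) and 2.02. The neural list had a median of 3.38 and 1.51 (percentile 98.8), with 3 of 5 members higher under both scalings, miR-128-3p and miR-132-3p (3.38 and 1.51) among them, and a mean of 0.14 on the size-factor scale. The other 2 members were lower on that scale. They were miR-132-5p, from the same hairpin as miR-132-3p, at -0.25 and -2.12, and miR-9-5p, named after its values were seen, at -1.26 and -3.10. miRNAs reported to promote breast cancer invasion had a median of 1.17 by CPM (percentile 2.21) but -0.74 by size factors (percentile 1.96), and it also lay below 0 with TMM factors. By CPM 10 of 16 were higher and 2 lower, and by size factors 1 was higher and 6 lower. This list holds miR-1246, miR-1290 and miR-122-5p, and the list of reported suppressors holds miR-200c-3p. miRNAs reported to suppress invasion had a median of 2.47 and 0.57 (percentile 89.2). miR-21-5p had folds of -0.57 (-0.58 to -0.56) and -2.50, lower under both scalings but less than 2-fold by CPM.

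The lists of other families and cell types lay within the range of random lists in KD over Control, and their medians by CPM and on the size-factor scale were as follows. The medians were 1.72 and -0.19 for the miR-17-92 family clusters (percentile 23.2), 2.03 and 0.11 for the miR-183 cluster (36.9), and 1.65 and -0.27 for the miR-30 family (11.8). They were 0.49 and -1.27 for the miR-29 family (4.86), 1.22 and -0.68 for the miR-15/16 family (4.03), and 1.51 and -0.33 for let-7 (4.09). The miR-23/24/27 clusters had 2.27 and 0.42 (64.1), the cluster of miR-221 and miR-222 2.04 and 0.11 (39.6), and the miR-320 family 2.61 and 0.69 (81.7). miRNAs of luminal breast cells had 2.20 and 0.30 (65.7), and those of mesenchymal and endothelial cells 2.24 and 0.39 (66.4). Blood cell miRNAs, markers of RNA from another source, had 0.92 and -0.99 (10.0) over 3 tested members. Their member miR-142-3p was lower in KD under both scalings, -1.17 and -3.03, on 169 reads in Control and 21 in KD. miR-142-5p, from the same hairpin, gave the median, and miR-486-5p was at 2.08 and 0.23. The miR-34 family had 1 tested member, at 1.23 and -0.68, and the liver list had miR-122-5p alone. Muscle miRNAs, the placental cluster on chromosome 19 and the miR-371-373 cluster had 0 tested members, with 6, 6 and 1 detected.

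RE and Control differ in the transfected construct, and their comparison asks how exosomes of cells given the LSD1 plasmid differ from those of Control. Control cells received a non-targeting siRNA, and no library came from cells given an empty plasmid. An effect of plasmid transfection therefore cannot be told apart from one of LSD1, here or in RE over KD. miR-1290 was higher in RE, at 24408 CPM against 1664 in Control, with log2 folds of 3.87 (3.82 to 3.92) and 3.65. It lies at chromosome 1, 18897071 to 18897148 on the minus strand, in an intron of ALDH4A1. miR-423-5p, at 4.88 (4.74 to 5.03) and 4.65, and miR-375-3p, at 4.80 (4.54 to 5.14) and 4.59, were higher in RE as in KD. Lower in RE were miR-21-5p, at -1.78 (-1.79 to -1.77) and -2.01, let-7f-5p, at -3.25 (-3.31 to -3.20) and -3.48, and let-7a-5p, at -2.99 (-3.06 to -2.93) and -3.22. The 10 miRNAs with the lowest folds, among those with a mean of at least 50 CPM, were all predicted names, with log2 folds by CPM from -8.75 for novel_miR_108 to -6.26. Some had nearly equal counts, such as novel_miR_130, novel_miR_74 and novel_miR_133, with 13294, 13148 and 13296 reads in Control and 203, 201 and 214 in RE. Such names may count the same reads more than once.

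By CPM, 111 tested miRNAs were at least 2-fold higher in RE than in Control and 105 lower, and under each of the 4 scalings 100 were higher (92 known) and 105 lower (48 known). Each of the 6 tested members of the miR-200 family was higher in RE under both scalings, with medians of 2.30 and 2.08 (percentile 99.1). miR-200c-3p had folds of 2.68 and 2.46 and miR-429 of 2.47 and 2.25. The let-7 family had 7 of 14 members lower and 2 higher under both scalings, with medians of -0.92 and -1.14 (percentile 0.5). let-7b-5p was one of the higher members, at 2.57 (2.496 to 2.64) and 2.34, and the 3p product let-7a-3p was the other, at 1.69 on the size-factor scale. Reported suppressors of invasion had medians of 1.93 and 1.71 (percentile 99.5), with 8 of 12 higher by CPM and 7 by size factors. Among them miR-148a-3p (1.87 and 1.65) and miR-146a-5p (2.08 and 1.86) were higher and miR-126-3p, an endothelial miRNA, was lower (-1.51 and -1.74). Reported promoters had medians of -0.05 and -0.28 (percentile 10.2). The chromosome 14 cluster again had 5 of 5 tested members higher, with medians of 2.69 and 2.62 (percentile 99.0), and its sum over 43 detected members had folds of 3.25 (2.78 to 3.75) and 3.02. Blood cell miRNAs had medians of -1.38 and -1.61 (percentile 3.58) over 3 tested members. miR-142-5p, which gave these medians, and miR-142-3p (-3.93 and -4.23) come from 1 hairpin. miR-486-5p went the other way, at 1.19 and 0.99, with 26 reads in Control and 81 in RE. miR-92a-3p, of the miR-17-92 clusters, was higher at 2.53 (2.49 to 2.58) and 2.31. The trend with GC was also present, with a Spearman rho of 0.32.

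**Figure D2:**
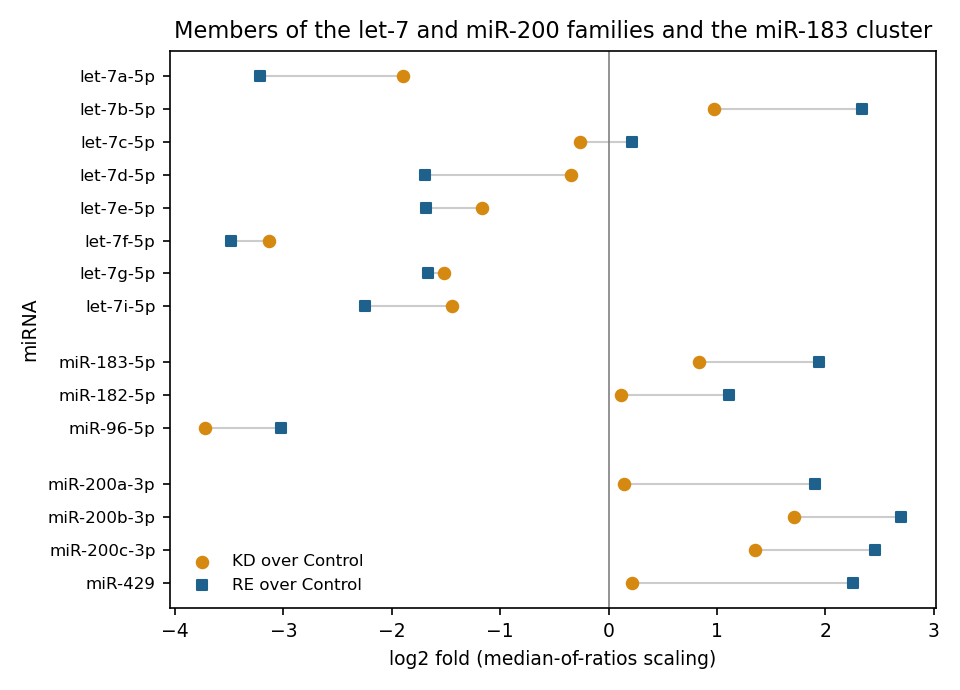
Log2 fold on the size-factor scale (horizontal axis) for members of the let-7 family, the miR-183 cluster and the miR-200 family, with circles for KD over Control and squares for RE over Control. In RE miR-200c-3p lies at 2.46 and let-7b-5p at 2.34, both also above 0 by CPM, and in KD let-7i-5p lies at -1.45 here against 0.48 by CPM.

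Whether the RE library returned toward Control was asked of the 244 miRNAs that differed at least 2-fold between KD and Control by CPM. In RE, 94 of them (38.5%) lay within 2-fold of Control, 130 stayed on the KD side and 20 lay on the opposite side. On the size-factor scale 18 of 169 (10.7%) lay within 2-fold and 142 stayed on the KD side. miR-375-3p, miR-423-5p, let-7f-5p, miR-96-5p and miR-29b-3p stayed on the KD side under both scalings. miR-1246 was within 2-fold of Control in RE, at 0.95 and 0.72. Among those on the opposite side under both scalings were novel_miR_128 and, in the other direction, novel_miR_51 and novel_miR_117, with identical counts in each library, at -2.25 in KD and 1.25 in RE by CPM. Both comparisons use the same Control library, so 100 sets of unchanged libraries were simulated. With counting error alone 98.6% of a mean of 6.98 called miRNAs returned, and with an assumed extra coefficient of variation of 0.4 the share was 63.5% of 88.7. Neither setting matches the data, since both called far fewer than 244 miRNAs and held no shift in composition between libraries. The simulated share was also lower with the larger spread. These shares therefore cannot show whether RE returned more or less than unchanged libraries would.

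Across the tested miRNAs, the log2 folds of KD and of RE over Control had a Pearson r of 0.76 and a covariance of 3.39. The simulated values without effects were 0.34 and 0.0239 with counting error alone, and 0.47 and 0.367 with the extra spread. By CPM, 104 miRNAs were at least 2-fold higher in both, against 72.8 for independent lists and 18.9 in the simulation with extra spread. There were 26 lower in both, against 9.28 and 11.9. The balance turned with the scaling: 76 were higher and 66 lower in both with TMM factors, against 31.8 and 25.1 for independent lists, and 57 were higher and 85 lower with size factors, against 20.4 and 36.4. With 1 Control library the controls cannot be split, and part of the excess may come from that shared library. The simulated libraries were less spread than these, so they do not limit how large that part may be.

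**Figure D3:**
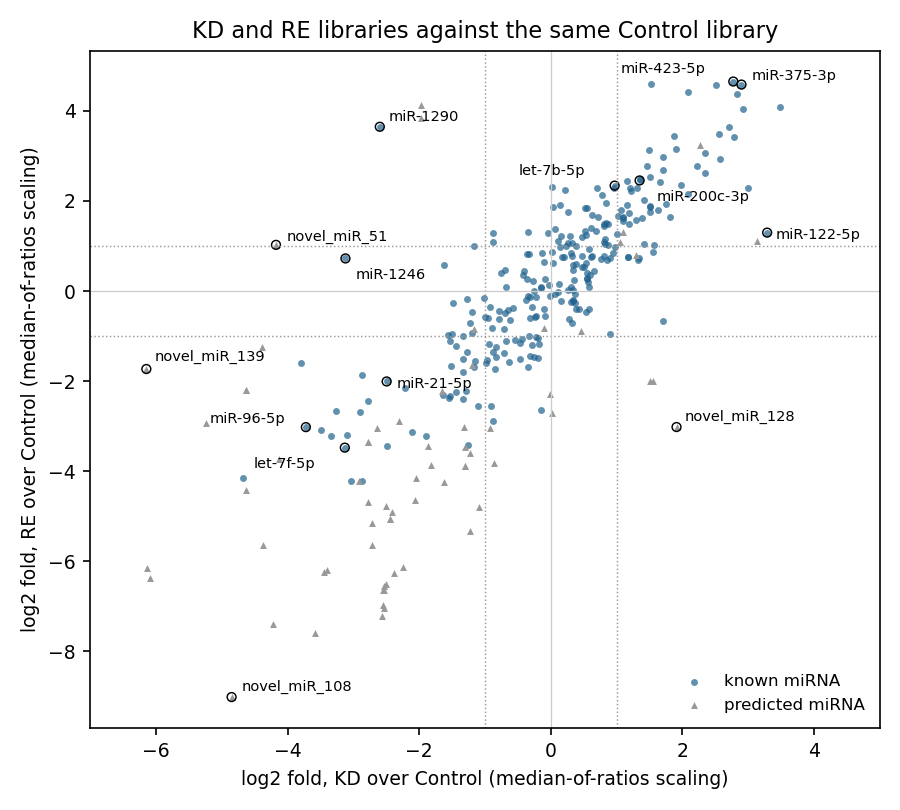
Log2 fold of RE over Control (vertical axis) against that of KD over Control (horizontal axis), both on the size-factor scale, for the 328 tested miRNAs. Circles are known and triangles predicted miRNAs, dotted lines mark 2-fold, and miR-1290 lies at -2.60 and 3.65 while miR-375-3p lies at 2.90 and 4.59.

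The comparison of RE with KD sets cells given the LSD1 plasmid against cells given the LSD1 siRNA. If RE cells also received the siRNA, which the labels do not say, it is of the siRNA with and without the plasmid. miR-1290 was higher in RE by a log2 fold of 4.55 (4.44 to 4.67) by CPM and 6.25 on the size-factor scale, from 1040 CPM in KD to 24408 in RE. miR-1246 was higher by 2.15 (2.13 to 2.16) and 3.85, and lies at chromosome 2, 176600980 to 176601052 on the minus strand, outside annotated genes on that strand. Its hairpin shares 19 nt, AATGGATTTTTGGAGCAGG, with the U2 spliceosomal RNA gene RNU2-1, and the miR-1290 hairpin shares 12 nt, TGGATTTTTGGA. The longest match among 239 other hairpins was 11 nt. miR-122-5p was lower in RE, at -3.66 (-4.24 to -3.25) and -1.99, and let-7a-5p was lower at -3.02 (-3.10 to -2.94) and -1.32.

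By CPM 9 tested miRNAs were at least 2-fold higher in RE than in KD and 236 lower. The split was 21 to 145 without the 5 most abundant names, 43 to 78 with TMM factors and 58 to 65 with size factors. Under each of the 4 scalings 9 were higher and 65 lower, and the 3 known miRNAs among the higher were miR-1246, miR-1290 and miR-95-3p. The last, named after its values were seen, had 18 reads in KD and 229 in RE. Of the listed fragments of other RNA classes 14 were detected but only 2 tested, miR-1246 and miR-1290, with medians of 3.35 and 5.05. These medians describe the 2 names and not the class. The miR-200 family had a median of -0.45 by CPM but 1.22 by size factors, and it was also above 0 with TMM factors and without the 5 most abundant names. The CPM median lay at percentile 99.6 of random lists, which carry the same scaling. Reported suppressors of invasion likewise went from -0.72 by CPM (percentile 99.3) to 0.96 by size factors. The let-7 median was -2.10 and -0.47 (percentile 0.95), with 12 of 14 members at least 2-fold lower and none higher by CPM, but by size factors 2 lower, 2 higher and 10 between. let-7b-5p was one of the higher members on that scale, at 1.37, and it was at -0.33 by CPM. The other was the 3p product let-7a-3p, at 1.07 on the size-factor scale. miR-21-5p was lower by CPM, at -1.21, and higher by size factors, at 0.49, and with TMM factors. The Spearman rho with GC was 0.02 for this pair.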

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

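The total of known miRNAs, the summed chromosome 14 cluster, the restrictions to known miRNAs, the removal of fragments with the total kept, the thinned libraries and the removal of identical predicted names were chosen after seeing the data. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. The cause of each shift below was not tested except where the setting itself changes how many miRNAs enter. KD over Control gave 215 higher and 29 lower by CPM, 94 and 77 with TMM factors, and 67 and 102 with median-of-ratios factors. The lower count was 57 without the 5 most abundant names, 55 with the total of known miRNAs, 49 at a 1.5-fold limit and 16 at 4-fold. Among known miRNAs only it was 11 of 259 tested with the library total kept, and 19 of 282 when the total, and with it the filter, was recomputed over known miRNAs. With no filter the counts were 567 and 63, and with a 100 CPM filter 102 and 13. RE over Control, 111 and 105 by CPM, became 270 and 175 with no filter and 57 and 48 at 100 CPM. It had 50 higher at a 4-fold limit and 48 lower among known miRNAs with the total kept, or 57 with it recomputed. RE over KD, 9 and 236 by CPM, became 43 and 78 with TMM factors, 58 and 65 with median-of-ratios factors, 21 and 145 without the 5 most abundant names, 70 and 528 with no filter, and 5 and 104 at 100 CPM. Its higher count was 15 at a 1.5-fold limit, 18 with the total of known miRNAs and 3 among known miRNAs with the total kept. Leaving out the fragments of other RNA classes gave 14 of 340 tested with the total recomputed and 7 with it kept. Its lower count was 118 at a 4-fold limit and, among known miRNAs, 178 with the total kept and 112 with it recomputed. The share returning to within 2-fold of Control, 38.5% by CPM, was 12.3% with TMM factors, 10.7% with median-of-ratios factors, 26.1% without the 5 most abundant names, 50.4% with a pseudocount of 10 CPM, and 20.9% when the limit was 1.5-fold.

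Of all 244 tested miRNAs at least 2-fold different by CPM in KD over Control, 25 changed sign with TMM and 61 with median-of-ratios factors. For RE over KD it was 58 and 85 of 245, for RE over Control 0 of 216 with either, and without the 5 most abundant names 0 in each comparison. Among the 155 folds of single miRNAs followed here by name and comparison, and the lists outside the range of random lists by CPM, such a turn was seen in 14 cases, with TMM, median-of-ratios or no-top-name scaling. The miR-200 median for RE over KD became 0.9996, 1.22 and 0.28 in that order, and that of reported suppressors of invasion 0.74, 0.96 and 0.015. For KD over Control the median of reported promoters became -0.32 with TMM and -0.74 with median-of-ratios factors, and miR-126-3p -0.43 and -0.85. miR-29a-3p became -0.36 and let-7d-5p -0.35 with median-of-ratios factors. miR-21-5p for RE over KD became 0.26 with TMM and 0.49 with median-of-ratios factors. Of the other values, 156 list medians and 428 named folds stayed within their counting or list range, and 136 and 341 moved further. Of all these, 34 list medians (in 23 of 51 results) and 33 named folds (in 12 of 155) also changed sign, from values smaller than 2-fold or lists inside the random range by CPM. Depth limits miRNAs near 5.10 CPM in KD, where a floor of 3 counts lies.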

Other observations

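The tests of a few dominant names, of U2 fragments and of GC as the whole cause were chosen after the result was seen, and the arm ratios below were also picked after their values were seen. Many hairpins yield a mature miRNA from each side, and the ratio of the 5p to the 3p product within a library needs no scaling. Of 25 hairpins with at least 20 reads from each arm in every library, 10 had a ratio at least 2-fold different in KD from Control, 2 toward the 5p and 8 toward the 3p product. In RE 16 did, 3 toward 5p and 13 toward 3p. For miR-423 the ratio was 0.0900 in Control (counting interval 0.0811 to 0.0996), 0.322 in KD (0.309 to 0.335) and 1.27 in RE (1.24 to 1.30). For miR-424 it was 1.62 in Control (1.30 to 2.02), 0.0804 in KD (0.0502 to 0.123) and 0.125 in RE (0.0913 to 0.167). For miR-330 it was 2.98 (2.37 to 3.78), 0.390 (0.310 to 0.488) and 0.187 (0.147 to 0.234). For miR-22 it was 0.0390 in Control (0.0292 to 0.0510), 0.0465 in KD (0.0377 to 0.0567) and 0.241 in RE (0.215 to 0.270). No explanation of these ratios was tested.

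Most miRNAs were higher in KD than in Control by CPM, 88.1% of those that differed at least 2-fold. With Control thinned to the KD total the share was 88.3%, with 276 miRNAs tested. Random thinning leaves the expected CPM of each name unchanged, so this argues only against counting noise and the filter at lower depth. It cannot decide any other effect of depth. CPM divides a fixed total among names, so abundant names that were lower in KD raised the CPM of the others by arithmetic. Such names were novel_miR_139, at 219010 CPM in Control and 11706 in KD, and miR-1246, at 152830 and 66592. How much of the split this makes up was not decided. With the 5 most abundant names left out of the total the share was 73.9%, and the median log2 fold was 0.98 in place of 1.74. Those names include miR-100-5p, which went the other way, from 25363 to 173857 CPM. They include only 1 of novel_miR_117 and novel_miR_51, which tie for the last place with identical counts. The other, at 67115 CPM in Control and 14064 in KD, stayed in the total, so the removal of dominant names was incomplete. TMM and median-of-ratios factors centre the folds by construction, so their more even splits say nothing of the cause. Whether abundant names were scarcer in KD exosomes, whether the other miRNAs were more abundant, or whether library preparation differed is open, and the LSD1 knockdown is untested as the cause with 1 library per group.

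miR-1246 and miR-1290 were both lowest by CPM in KD and highest in RE. Both hairpins share sequence with U2 RNA, so fragments of a U2-like RNA may be counted under either name. If one RNA gave both in a fixed proportion, their ratio would be equal in each library, but there were 0.0109 reads of miR-1290 per read of miR-1246 in Control and 0.0827 in RE, 7.59 times as many. This argues against a single source in fixed proportion for the RE library, not against fragments as such. In KD the ratio was 0.0156, 1.43 times that of Control (1.28 to 1.61 from the counting intervals), which leaves a common source open for the lower values in KD. An effect of LSD1 on either miRNA stays open and untested.

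Members of let-7 and other families moved apart in KD and RE. A GC-dependent bias between libraries is a candidate contributor, with a Spearman rho between GC and the size-factor log2 fold of 0.43 for KD over Control and 0.32 for RE over Control. After a straight-line GC trend was removed, 94.4% of the SD over the 14 let-7 members, 3p products included, was left in KD and 96.9% in RE. The gap between let-7b-5p and let-7f-5p went from 4.10 to 3.13 log2 units in KD and from 5.82 to 4.91 in RE. These values cannot decide whether GC was the whole cause. The line, fitted over 257 miRNAs, had an r2 of 18.3% in KD and 9.61% in RE. The SD over those miRNAs also went only from 1.39 to 1.25 in KD and from 1.79 to 1.70 in RE. The GC used was that of a hairpin side, or of the whole hairpin for names that give no side, not of the mature sequence. Reads assigned differently among near-identical members, ligation preference and an effect of the treatments were not tested and stay open.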
